A study of Arabidopsis thaliana with 8 samples.

How the data were processed

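Inflorescences of Col-0 and dbr1-2 plants, grown at 22 °C with 16 h of light and 8 h of dark, were the source of total RNA extracted with Trizol, per the labels' protocols. Ribosomal RNA was depleted, and in 2 of the groups the RNA was digested with RNase R for 2 h at 37 °C before recovery and preparation of stranded libraries for an Illumina HiSeq instrument, per the labels' protocols. The sequencing tags of 7 libraries also name removal of mRNA. That of dbr1-2 replicate 1 with RNase R names ribosomal RNA alone, and whether this library was prepared differently is not given in the sources used here. TopHat2 2.0.13, Cufflinks 2.2.1, Cuffnorm 2.2.1 and the TAIR10 genome are named per the submitters' processing notes, which give no order or settings. The values are FPKM that the authors deposited, 1 value per locus and library. Whether Cuffnorm scaled the libraries to each other, and whether counting used the strand, is not given in the sources used here.

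The table holds 32232 loci, of which 31589 carry 1 gene name, 378 several and 265 none. The names were matched to the TAIR10.1 reference annotation (nuclear sequence as in TAIR10), which gave coordinates for 30924 loci, all overlapping the annotated gene. Of 30266 matched loci with a name used once, 99.92% had a locus number that follows the order of genes on their annotated strand. From that numbering, 364 loci stood on the strand opposite the gene they are named after, 340 of them with a name that occurs more than once. This strand is inferred, not given. In all, 6866 loci share their interval with another locus, and reads of overlapping genes and of similar copies in gene families may have been divided between them, so such values are uncertain. Overlap with an annotated gene is marked below for only part of the named genes. RS41, SPL15, SPL4, UBC21, RS40, STK, CSD1 and AT5G26990 also overlap a gene on the other strand, and DCL1 overlaps genes on both strands.

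FPKM carries no read counts, but low values come in steps of whole reads. With transcript lengths reduced by 199 nt, 95.3% to 99.8% of low values lay within 0.05 of a whole number of reads. A single read was worth 0.0111 to 0.0133 FPKM on 1 kb of such reduced length without RNase R and 0.0788 to 0.116 with it. The worth of 3 reads was 0.0332 to 0.04 and 0.236 to 0.348, so low values are far less precise with RNase R. An exact 0 can be a failed estimate: 7 loci exceeded 1000 FPKM in 1 library and were at 0 in another, and 11 were at 0 in 1 replicate of a group and at 50 FPKM or more in the other, 14 times in all. Such loci are given as listed, per library.

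Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with lmFit, contrasts and eBayes with a trend, over the 14351 loci with at least 1 FPKM in at least 2 of the 8 libraries. All 8 libraries entered 1 fit, with 4 residual degrees of freedom and no covariate, and calls needed a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each of 5 comparisons. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low loci. The interaction can instead be overstated on this scale, where FPKM is lower in 1 genotype and its change is shrunk more. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

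The design, tests, alternatives, naming rule and 12 gene lists were set before the data were examined. The lists cover splicing factors, small RNA machinery, miRNA targets, floral identity and meristem, tapetum and pollen wall, mature pollen, green tissue photosynthesis, housekeeping, immune response, abiotic and heat stress, RNA decay and surveillance, and TAS and IPS non-coding RNAs. Of their 220 genes, 211 are in the table under their own name. These lists and 15 annotation classes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, where at least 3 members were tested. Camera compares a set with other loci, whereas fry tests whether its members move, on balance, in 1 direction.

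The text names DBR1 and, per comparison, genes past the threshold with a mean FPKM of at least 5, at least 300 nt of exon and no overlap between the groups compared (not asked for the interaction). Of these the rule takes the 10 largest rises and falls among protein-coding genes and the 5 largest among other loci. It adds up to 4 members per list with the smallest p, for which no minimum of FPKM, exon length or separation was asked, so some are well below 5 FPKM. The text describes a subset from the top of each ranking. Alternatives were pseudocounts of 0.1 and 0.01, no filter, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, TPM, removal of organelle and ribosomal RNA loci with rescaling, removal of loci under 300 nt, other eBayes settings, array weights, only the 4 libraries compared, the replicate block, the tag year, a minimum log2 fold change of 1, and each library left out in turn. Removal of loci with doubtful zeros was added after the data had been seen.

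The replicate number marks a shared tag date in the groups without RNase R, where deviations of same-numbered libraries from their group means correlated at 0.303 across loci, against −0.051 to 0.083 for other pairs of groups. With the replicate block, 1781 loci passed between genotypes without RNase R. The test was tried on simulated data with 200 of 14351 loci changed, placed above a minimum mean level, and with equal spread in all libraries. At a log2 change of 1 it recovered 94% without RNase R and 95% with it between genotypes, 93% for RNase R in each genotype and 78% for the interaction. False calls were 4.4%, 4%, 5.9%, 5% and 9.7% in that order of comparisons. The data differ: array weights, lower where libraries scatter more, were 2.01 to 2.44 without RNase R and 0.403 to 0.507 with it. These rates therefore do not cover unequal spread between groups or low loci.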

Results

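Ribosomal RNA-depleted RNA from inflorescences of Arabidopsis thaliana was sequenced in 8 libraries. They form 4 groups of 2 libraries: wild-type Col-0 and the mutant dbr1-2, each with and without digestion by RNase R. Most of the sequencing tags also name removal of mRNA. Values of protein-coding genes may therefore depend on how much mRNA that step left, which was not tested. DBR1 encodes the lariat debranching enzyme, which opens the branched loop that splicing leaves of an excised intron. RNase R is an exonuclease that degrades linear RNA, while the loop of a lariat and circular RNA resist it. The title of the series names intron branchpoints and lariat RNAs as its subject. The design implies 5 comparisons: dbr1-2 against Col-0 without and with RNase R, RNase R against none in each genotype, and the interaction of genotype and RNase R.

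The table lists 32232 loci with their FPKM, of which 14351 passed the expression filter and were tested. The FPKM summed to between 295494 and 384482 per library without RNase R and to between 2796449 and 4003096 with it. The steps between low values showed that 1 FPKM on 1 kb of transcript, counted after taking off 199 nt, stood for 75 to 90.4 reads without RNase R. With RNase R it stood for 8.6 to 12.7 reads. Protein-coding loci held 26.9% to 32.2% of the FPKM total without RNase R and 3.84% to 4.91% with it. Small nuclear RNA (snRNA) loci held 10.5% to 19.9% without and 26.0% to 41.7% with RNase R, and chloroplast loci held 45.3% to 47.9% and 42.6% to 58.1%. With RNase R, the snRNA locus U1.5 alone held 25.96% to 41.58% and the chloroplast gene psbM 23.04% to 31.8% of the total. The shares thus rest on a few loci and do not measure how much mRNA was lost. Across loci, which are not independent replicates, Spearman's rho between the 2 libraries of a group was 0.978 in Col-0 and 0.979 in dbr1-2 without RNase R, and 0.903 and 0.941 with it. The labels do not say whether the libraries of a group came from separate plants, and their sequencing tags carry the same sample code within a genotype, so the p-values may measure technical spread only.

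DBR1 (AT4G31770) lies on the minus strand of chromosome 4 from 15370061 to 15372942 in the TAIR10.1 annotation and has 8 introns. Its FPKM was 0.662 and 0.694 in the Col-0 libraries without RNase R and 0.339 and 0.43 in those of dbr1-2. With RNase R it was 0.202 and 0.188 in Col-0 and 0.265 and 0.26 in dbr1-2. These values lie below the expression filter. In the limma fit without that filter, DBR1 was lower in dbr1-2 without RNase R (log2 fold change −0.28, SE 0.05, adjusted p = 0.0306), while the difference with RNase R did not pass (0.08, SE 0.05, adjusted p = 0.355). What the mutation does to the transcript is not given in the sources used here.

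Without RNase R, the comparison of genotypes asks which RNAs differ in inflorescences of the mutant. ELIP1 (AT3G22840, chromosome 3 from 8084405 to 8085669), an early light-induced protein of the chloroplast, rose from 5.31 ± 0.49 FPKM in Col-0 to 46.5 ± 0.11 in dbr1-2 (SD, n = 2 each; log2 fold change 2.91, SE 0.12, limma adjusted p = 3.6e-05). LTP4 (AT5G59310, chromosome 5 from 23924990 to 23925957), a lipid transfer protein, rose from 104 ± 10 to 656 ± 44 FPKM. NIA2 (AT1G37130, chromosome 1 from 14158452 to 14161938), a nitrate reductase, rose from 1.86 ± 0.095 to 13.2 ± 0.33 FPKM, and P5CS1 (AT2G39800, chromosome 2 from 16598072 to 16603319), an enzyme of proline synthesis, from 12.8 ± 0.67 to 62.0 ± 1.5. GRP7 (AT2G21660, chromosome 2 from 9265084 to 9266557), a glycine-rich RNA-binding protein under control of the circadian clock, fell from 199 ± 26 to 60.6 ± 9.2 FPKM (log2 fold change −1.70, SE 0.14, limma adjusted p = 0.000512). XTH9 (AT4G03210, chromosome 4 from 1415617 to 1417444), a cell wall enzyme acting on xyloglucan, fell from 79.3 ± 4.3 to 30.7 ± 1.8 FPKM.

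**Figure D1:**
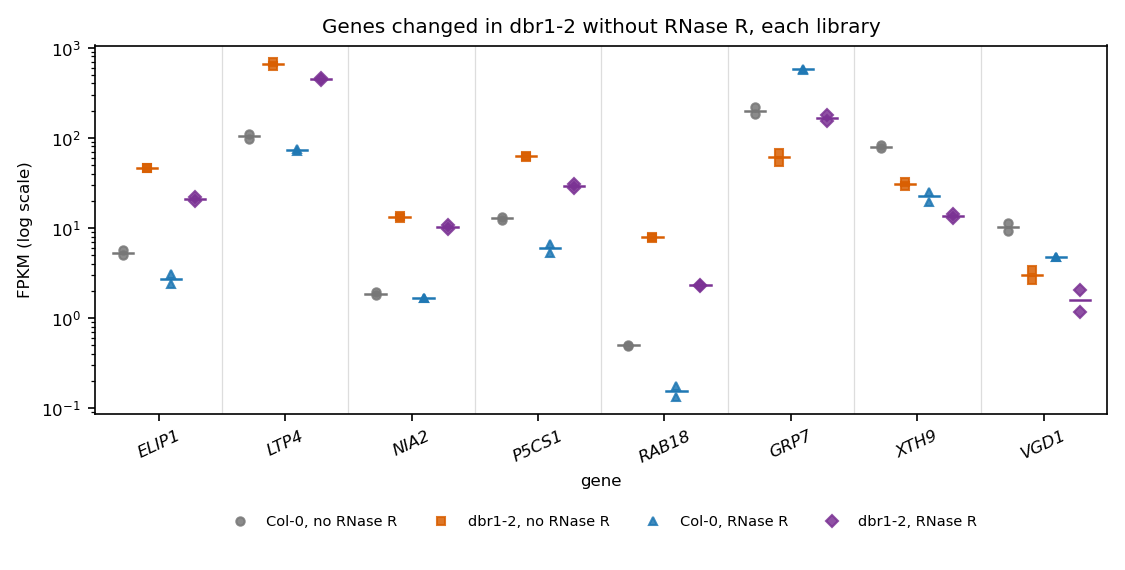
FPKM on a log scale of 8 genes in each of the 8 libraries, with a bar at the mean of each group of 2. Without RNase R, ELIP1, LTP4, NIA2, P5CS1 and RAB18 are higher in dbr1-2 and GRP7, XTH9 and VGD1 are lower, with no overlap between the groups.

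The largest rises among protein-coding genes in dbr1-2 without RNase R were those of AT3G53980 (log2 fold change 3.22, SE 0.19), the cytochrome P450 gene CYP71B31 (2.97, SE 0.14), ELIP1, AT3G28270 (2.67, SE 0.23), LTP4 (2.65, SE 0.11), AT4G03360 (2.64, SE 0.56), NIA2 (2.31, SE 0.09) and P5CS1 (2.19, SE 0.11). The largest falls were those of AT4G30650 (−1.90, SE 0.20), GRP7, PGA4, a polygalacturonase of pollen (−1.47, SE 0.15), AT5G19580 (−1.41, SE 0.13), AT4G11320 (−1.35, SE 0.11), the cold-regulated gene COR15B (−1.35, SE 0.23) and XTH9 (−1.34, SE 0.13). AT4G03360 shares its listed interval with other loci, so its value is uncertain, and its libraries were far apart in Col-0 (87.5 and 371 FPKM), with a log2 fold change of 1.61 without Col-0 replicate 1 and 3.68 without Col-0 replicate 2. Its limma adjusted p of 0.0166 became 0.0645 without dbr1-2 replicate 1, 0.106 without dbr1-2 replicate 2 and 0.0603 without the expression filter. AT3G53980 lost its call with a pseudocount of 0.01 (adjusted p = 0.145). COR15B lost its call without Col-0 replicate 1 (adjusted p = 0.068) and without dbr1-2 replicate 2 (adjusted p = 0.0575). P5CS1 and COR15B overlap an annotated gene on the other strand, and since the sources do not say whether counting used the strand, their values are uncertain.

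Among other loci, some carry the name of a gene but stand on its other strand, as inferred from the numbering of loci, and are called opposite-strand loci here. The opposite-strand locus at AT1G78300 was listed at 0 in both Col-0 libraries without RNase R and at 8.99 and 7.8 FPKM in dbr1-2. The locus with the names AT5G24150 and AT5G24155 rose from 4.51 ± 0.46 to 23.9 ± 1.2 FPKM, and the opposite-strand locus at AT2G15580 rose by a log2 fold change of 2.02 (SE 0.20, limma adjusted p = 0.000815). The chloroplast gene psbA was listed at 10159 and 12106 FPKM in Col-0 without RNase R and at 0 in the other 6 libraries. The opposite-strand locus at AT3G06435 fell by 0.79 on the log2 scale (limma adjusted p = 0.00764), and its adjusted p was 0.0551 without Col-0 replicate 2 and 0.0691 without dbr1-2 replicate 1.

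In the list of abiotic and heat stress genes, 3 of 10 tested members rose, 1 fell and 6 did not pass (3 and 2 adjusted over the list alone; camera adjusted p = 0.759). RAB18, a dehydrin induced by abscisic acid, rose from 0.498 ± 0.014 to 7.84 ± 0.043 FPKM, and the chaperone gene HSP90.1 from 0.288 ± 0.074 to 1.67 ± 0.18. In the green tissue photosynthesis list, 6 of 16 rose, 3 fell and 7 did not pass (7 and 4 adjusted over the list alone; camera adjusted p = 0.434). Its rises included the carbonic anhydrase gene CA1 (49.4 ± 4.6 to 159 ± 2.6 FPKM), the Rubisco activase gene RCA (114 ± 6.1 to 290 ± 9.8), GAPA (74.6 ± 0.091 to 123 ± 2.8) and FNR1 (23.2 ± 1.3 to 43.5 ± 1.6). CA1 and GAPA overlap a gene on the same strand and RAB18, RCA and FNR1 a gene on the other, and the calls of RCA, GAPA and FNR1 were lost once organelle and ribosomal RNA loci had been removed and the rest rescaled, that of GAPA also as TPM. In the mature pollen list, all 4 tested members fell (4 adjusted over the list alone), by log2 fold changes of −1.48 (VGD1, a pectin methylesterase of pollen tubes), −0.48 (BUPS1), −1.27 (AGP11) and −0.93 (AGP6). That list was lower than other loci by camera (adjusted p = 1.91e-05). The call was lost with adjusted p = 0.631 with an estimated correlation. Leaving out 1 library ended 3 of these calls. Those of AGP11 (limma adjusted p = 0.0788 and 0.358) and AGP6 (0.139 and 0.239) were also lost with pseudocounts of 0.1 and 0.01, and that of AGP6 without the expression filter (0.0831) and with median ratios (0.0659). The limma adjusted p of AGP11 was 0.0753 without dbr1-2 replicate 1 and 0.0705 without dbr1-2 replicate 2. That of AGP6 was 0.17 without Col-0 replicate 2, 0.179 without dbr1-2 replicate 1 and 0.0953 without dbr1-2 replicate 2. That of BUPS1 was 0.0774 without Col-0 replicate 1, 0.106 without Col-0 replicate 2, 0.0884 without dbr1-2 replicate 1 and 0.11 without dbr1-2 replicate 2.

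Of 16 tested genes of floral identity and the meristem, 3 rose, 3 fell and 10 did not pass (4 and 4 adjusted over the list alone; camera adjusted p = 0.385). The floral organ gene SEP1 rose from 6.47 ± 0.019 to 10.2 ± 0.50 FPKM and the meristem gene STM from 5.15 ± 0.26 to 10.5 ± 0.51. SEP1 lost its call without organelle and ribosomal RNA loci (adjusted p = 0.385) and without Col-0 replicate 1 (0.0546), Col-0 replicate 2 (0.0518) or dbr1-2 replicate 1 (0.0702), and STM without Col-0 replicate 1 (0.0675) or dbr1-2 replicate 1 (0.0648). Of 36 microRNA (miRNA) targets, 4 rose, 3 fell and 29 did not pass (5 and 3 adjusted over the list alone; camera adjusted p = 0.385). GRF3, which like SEP1 overlaps genes on the other strand, stood at 3.8 ± 0.15 FPKM in Col-0 and 1.83 ± 0.13 in dbr1-2 (limma adjusted p = 0.0029). Of 23 splicing factors, 4 rose, 3 fell and 16 did not pass (4 and 3 adjusted over the list alone; camera adjusted p = 0.142). Of 14 housekeeping genes, 4 rose and 10 did not pass (5 and 1 adjusted over the list alone; camera adjusted p = 0.475). Of 12 genes of the tapetum and pollen wall, 1 rose and 11 did not pass (0 adjusted over the list alone; camera adjusted p = 0.151). Of 5 TAS and IPS non-coding RNAs, 1 rose and 4 did not pass (1 adjusted over the list alone; camera adjusted p = 0.759). By limma, 0 of 22 genes of the small RNA machinery passed (3 at an unadjusted p under 0.05; camera adjusted p = 0.308, fry adjusted p = 0.625). The same count was 0 of 15 for RNA decay and surveillance (2 unadjusted; camera 0.492, fry 0.504) and 0 of 4 for the immune response (1 unadjusted; camera 0.402, fry 0.337).

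In all, 2518 of 14351 loci passed without RNase R, 2042 higher and 476 lower in dbr1-2, with a median log2 fold change of 0.13 over all loci, relative to which ELIP1 stood at 2.78 and GRP7 at −1.83. Scaling each library by its median ratio took that median to 0.01 and left 1197 calls (760 higher, 437 lower). The splits were 1008 to 855 with quantile normalization, 1878 to 1277 as TPM, and 1105 to 657 after removal of organelle and ribosomal RNA loci. Under all 5 scalings, 530 loci were higher and 271 lower, and 0 were called in opposite directions. With only the 4 libraries compared 5847 loci passed (4703 higher, 1144 lower) and with array weights 6307 (5037 and 1270), while pseudocounts of 0.1 and 0.01 left 1467 and 1276. A mean FPKM of at least 5 left 934 and a minimum log2 fold change of 1 left 356. Leaving out 1 library left 823 calls (Col-0 replicate 1), 864 (Col-0 replicate 2), 819 (dbr1-2 replicate 1) or 863 (dbr1-2 replicate 2).

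With RNase R, the comparison of genotypes asks which RNAs left after digestion differ in the mutant. Such RNAs need not resist RNase R. RCA, for example, fell with it from 114 to 30.9 FPKM in Col-0 and from 290 to 71.7 in dbr1-2. Its log2 fold change between genotypes was 1.34 without RNase R and 1.19 with it. ADF11 (AT1G01750, chromosome 1 from 275188 to 276310), an actin-depolymerizing factor, rose from 1.13 ± 0.16 FPKM in Col-0 to 82.5 ± 4.8 in dbr1-2 (SD, n = 2 each; log2 fold change 5.30, SE 0.10, limma adjusted p = 3.77e-07). AT5G64160 (chromosome 5 from 25670930 to 25672710) rose from 11.9 ± 1.9 to 254 ± 11 FPKM, and AT1G23440 (chromosome 1 from 8321611 to 8324497) from 2.2 ± 0.033 to 51.4 ± 12. ARPC1B (AT2G31300, chromosome 2 from 13345977 to 13350004), a subunit of the Arp2/3 complex of actin branching, rose from 1.53 ± 0.54 to 34.1 ± 0.27 FPKM. TOE2 (AT5G60120, chromosome 5 from 24207689 to 24211743), an AP2-like transcription factor and miRNA target, rose from 3.13 ± 0.21 to 44.0 ± 0.84 FPKM. AT3G06435 (chromosome 3 from 1968288 to 1970946) fell from 48.3 ± 0.30 to 6.58 ± 0.13 FPKM (log2 fold change −2.70, SE 0.08, limma adjusted p = 2.11e-06).

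The largest rise among protein-coding genes with RNase R was listed for AT4G03360 (111 ± 0.26 to 25241 ± 2700 FPKM), the gene whose interval other loci share. After ADF11, AT5G64160 and AT1G23440 came AT5G57970 (log2 fold change 3.91, SE 0.67), ARPC1B (3.81, SE 0.15), DER1, a derlin of protein quality control in the endoplasmic reticulum (3.77, SE 0.19), and AT4G20320 (3.75, SE 0.13). The Col-0 libraries of AT5G57970 were far apart (7.47 and 0.417 FPKM), and its log2 fold change was 5.20 without Col-0 replicate 1 and 2.62 without Col-0 replicate 2. After AT3G06435, the largest falls were those of COR15B (−1.91, SE 0.23), GRP7 (−1.79, SE 0.14), AT5G22430 (−1.74, SE 0.09) and AT3G46630 (−1.58, SE 0.17). The opposite-strand locus at AT1G55325 rose from 5.90 ± 0.70 to 171 ± 1.1 FPKM, and the non-coding locus AT1G25098, which overlaps AT1G25112 on its own strand and is therefore uncertain, rose from 3.71 ± 0.34 to 107 ± 25. The chloroplast gene rbcL was listed at 39187 and 40535 FPKM in Col-0 with RNase R and at 0 in both dbr1-2 libraries, and the unnamed locus XLOC_022784 at 326 and 109 against 0 and 0. The opposite-strand locus at AT3G06435 fell from 133 ± 3.5 to 16.4 ± 2.0 FPKM. ADF11, AT5G64160, ARPC1B, AT5G57970 and AT3G06435 overlap annotated genes on the other strand and are uncertain in the same way.

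Of 23 splicing factors, 9 were higher in dbr1-2 with RNase R, 3 lower and 11 did not pass (9 and 3 adjusted over the list alone; camera adjusted p = 0.929). The SR protein genes RS31 (1.38 ± 0.11 to 4.66 ± 0.30 FPKM) and RS41 (4.20 ± 0.049 to 11.7 ± 2.2) and U2AF65A, a subunit of the factor that binds the 3′ end of introns (1.71 ± 0.21 to 6.78 ± 1.3), rose, while GRP7 fell. Of 36 miRNA targets, 7 rose, 6 fell and 23 did not pass (8 and 8 adjusted over the list alone; camera adjusted p = 0.0965). SPL15 stood at 0.762 ± 0.0051 and 5.27 ± 0.82 FPKM and PHV at 4.95 ± 0.12 and 2.68 ± 0.12. Of 22 genes of the small RNA machinery, 7 rose and 15 did not pass (10 and 4 adjusted over the list alone; camera adjusted p = 0.892). Among the rises were the Dicer-like genes DCL1 (log2 fold change 0.55) and DCL4 (0.58). Of 15 genes of RNA decay and surveillance, 4 rose, 1 fell and 10 did not pass (4 and 0 adjusted over the list alone; camera adjusted p = 0.954). Rises were those of RRP6L1, related to a nuclease of the exosome (log2 fold change 1.47), and the decapping gene DCP2 (0.63). The calls of DCL1, DCL4 and DCP2 were lost as TPM, after removal of organelle and ribosomal RNA loci and with the tag year as covariate (limma adjusted p = 0.0593, 0.0659 and 0.0744), that of DCL4 also with only the 4 libraries compared, and that of RS41 after the removal.

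Of 16 floral identity and meristem genes, 4 rose, 6 fell and 6 did not pass (4 and 6 adjusted over the list alone; camera adjusted p = 0.0966). FUL was higher (log2 fold change 0.99) and AP1 lower (−0.87) in dbr1-2. Of 16 green tissue genes, 7 rose, 3 fell and 6 did not pass (7 and 3 adjusted over the list alone; camera adjusted p = 0.929). CA1 (1.75) and RCA (1.19) were higher and the light-harvesting gene LHCB1.2 lower (−1.09). Removal of organelle and ribosomal RNA loci ended the calls of FUL and RCA. Of 10 abiotic and heat stress genes, 5 rose, 1 fell and 4 did not pass (5 and 1 adjusted over the list alone; camera adjusted p = 0.929). RAB18 (1.52) and the cold-regulated gene COR15A (0.72) were higher, the latter call lost in 3 of the 4 other scalings, with the tag year as covariate (limma adjusted p = 0.0589) and with only the 4 libraries compared (0.0527). Of 14 housekeeping genes, 4 rose, 3 fell and 7 did not pass (4 and 3 adjusted over the list alone; camera adjusted p = 0.369). UBC21, a ubiquitin-conjugating enzyme, had a log2 fold change of 1.33. Of 4 mature pollen genes, VGD1 fell (−1.16, limma adjusted p = 0.00149) and 3 did not pass (1 adjusted over the list alone; camera adjusted p = 0.0682). Of 12 tapetum and pollen wall genes, 1 rose, 1 fell and 10 did not pass (0 and 1 adjusted over the list alone; camera adjusted p = 0.353). By limma, 0 of 5 TAS and IPS RNAs (1 at an unadjusted p under 0.05; camera adjusted p = 0.467, fry 0.688) and 0 of 4 immune response genes (1 unadjusted; camera 0.929, fry 0.00799) passed.

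Among annotation classes with RNase R, mitochondrial loci were lower in dbr1-2 than other loci (6 higher and 19 lower of 68; camera adjusted p = 0.000125, and adjusted p = 0.621 with an estimated correlation). Genes with no intron were lower relative to other loci (312 higher and 155 lower of 1495; camera adjusted p = 0.0458, and adjusted p = 0.621 with an estimated correlation), although their median was 0.06. Small nucleolar RNA (snoRNA) loci were lower relative to other loci both with RNase R (0 higher and 2 lower of 12; camera adjusted p = 0.0218, and adjusted p = 0.621 with an estimated correlation) and without it (camera adjusted p = 0.0155, and adjusted p = 0.655 with an estimated correlation), where 0 of 12 passed in limma (1 at an unadjusted p under 0.05; fry 0.457). Of 310 opposite-strand loci, 217 were higher and 10 lower in dbr1-2 with RNase R (141 and 7 under all 5 scalings), with a median log2 fold change of 1.02. A locus could pass the expression filter through its libraries with RNase R alone. Counts of rises among these loci, here and below, therefore follow in part from the filter.

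In all, 5315 loci passed with RNase R, 4298 higher and 1017 lower in dbr1-2 (median log2 fold change 0.15, relative to which ADF11 stood at 5.14 and AT3G06435 at −2.85). The split was 3513 to 1978 with median ratios and with quantile normalization 2589 of 5660 calls were higher, while TPM left 1715 calls and removal of organelle and ribosomal RNA loci 1230. With only the 4 libraries compared 2633 loci passed (2335 higher, 298 lower), against 5847 without RNase R, and with array weights 3453 (3005 and 448). Which comparison of genotypes has more calls thus depends on the spread that the groups share in the main fit. A mean FPKM of at least 5 left 1771 and a minimum log2 fold change of 1 left 1368. Under all 5 scalings 919 loci were higher and 217 lower, and 6 were called in opposite directions. Both dbr1-2 libraries with RNase R carry tags of an earlier year than both Col-0 libraries, so genotype and library date cannot be told apart in this comparison, and with the year as covariate, estimated from the libraries without RNase R, 2423 calls were left. Without dbr1-2 replicate 1 with RNase R, the library whose tag names no removal of mRNA, 5171 loci passed, 3869 higher and 1302 lower. Calls in both comparisons of genotypes numbered 1272 higher (611.6 for independent lists) and 239 lower (33.7), from 1 fit with a common spread per locus. From separate fits of 4 libraries each they numbered 1225 higher (765.2) and 165 lower (23.8). Since the tags carry the same sample code within a genotype, the lists are not independent and these values are no measure of chance.

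RNase R against none in Col-0 asks which RNAs rose or fell in FPKM with digestion in wild type. FPKM is a relative value, so a rise does not by itself show resistance, and directions can turn with the scaling. The ribosomal protein gene RPL23AA (AT2G39460, chromosome 2 from 16474149 to 16476141) fell from 56.9 ± 2.8 FPKM to 1.13 ± 0.32 (SD, n = 2 each; log2 fold change −4.77, SE 0.12, limma adjusted p = 2.59e-07). AT2G25210 (chromosome 2 from 10739855 to 10740552), a gene of the L39 ribosomal protein family, fell from 40.1 ± 3.7 to 0.494 ± 0.095 FPKM, and AT3G60245 (chromosome 3 from 22268688 to 22270028), of a zinc-binding ribosomal protein family, from 69.4 ± 17 to 1.52 ± 0.070. The metallothionein gene MT2B (AT5G02380, chromosome 5 from 506498 to 507244) fell from 100 ± 5.3 to 2.61 ± 0.69 FPKM. AT2G31141 (chromosome 2 from 13271726 to 13272534) rose from 802 ± 44 to 48507 ± 910 FPKM (log2 fold change 5.92, SE 0.18), the response regulator gene RR3 (AT2G41310, chromosome 2 from 17221840 to 17224880) from 619 ± 140 to 34482 ± 460, and the beta-xylosidase gene BXL3 (AT5G09730, chromosome 5 from 3014894 to 3018342) from 71.3 ± 15 to 3912 ± 50. AT2G31141 and RR3 overlap genes on the other strand.

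Next among the rises were AT4G23420 (log2 fold change 4.68, SE 0.44; 5.32 without Col-0 replicate 1 and 4.04 without Col-0 replicate 2, both without RNase R), which overlaps an annotated snRNA on its own strand, and AT1G49700 (4.60, SE 0.10). The largest fall was that of AT2G35750 (−7.19, SE 0.24), which overlaps snoRNAs on its own strand, so both overlapped genes are uncertain. AT3G11120, of the L41 ribosomal protein family, was at 64.6 and 49.0 FPKM without RNase R and listed at 0 in both Col-0 libraries with it. Among other loci, rbcL was at 8804 FPKM and listed at 0 without RNase R and at 39187 and 40535 with it, and psbA at 10159 and 12106 without RNase R was listed at 0 with it. The opposite-strand locus at AT1G78300 was listed at 0 in both Col-0 libraries without RNase R and at 159 and 174 FPKM with it. The chloroplast gene rps14, a ribosomal protein, rose from 2321 ± 230 to 161500 ± 4400 FPKM (log2 fold change 6.12, SE 0.20).

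**Figure D2:**
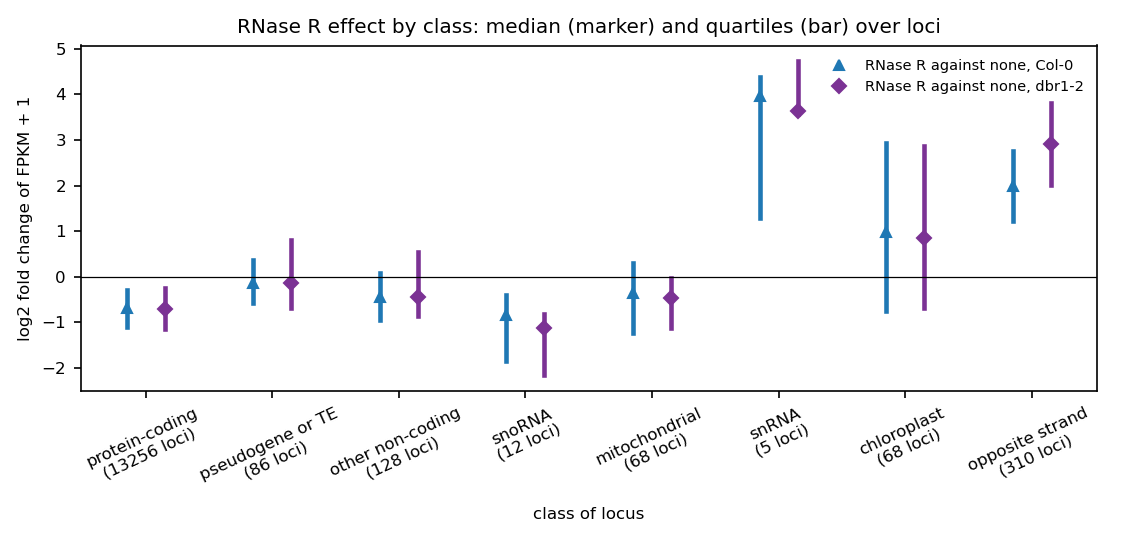
Median (marker) and quartiles (bar) of the log2 fold change of FPKM + 1 with RNase R over the tested loci of 8 classes, in Col-0 and in dbr1-2. Protein-coding loci lie below 0, with medians of −0.69 and −0.72, and opposite-strand loci above it, with medians of 2.00 and 2.91, while as TPM the median over all tested loci was −2.67 and −2.69.

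Of 13256 protein-coding loci, 739 rose with RNase R in Col-0 and 9773 fell, of which 21 and 3731 did so under all 5 scalings (camera adjusted p = 1.37e-33 for a shift below other loci, and adjusted p = 0.0531 with an estimated correlation). Chloroplast loci were higher relative to other loci (38 higher, 22 lower of 68; camera adjusted p = 8.28e-21, kept with adjusted p = 0.0153 with an estimated correlation), a call whose direction turned with quantile normalization (adjusted p = 0.973). Other classes higher relative to other loci were snRNA (3 higher of 5; camera adjusted p = 5.14e-05, and adjusted p = 0.287 with an estimated correlation) and pseudogenes and transposable elements (24 higher, 33 lower of 86; camera 2.27e-07, and adjusted p = 0.156 with an estimated correlation). MIR primary transcripts were too (3 higher, 4 lower of 13; camera 0.00308, and adjusted p = 0.156 with an estimated correlation). The same held for mitochondrial loci (14 higher, 31 lower of 68; camera 0.00164, and adjusted p = 0.481 with an estimated correlation) and other non-coding RNA (22 higher, 72 lower of 128; camera 0.00525, and adjusted p = 0.424 with an estimated correlation), whose medians of −0.35 and −0.44 lay below 0. Of 310 opposite-strand loci, 276 rose and 11 fell, with a median of 2.00. They are among the few loci that camera set against protein-coding ones, and the filter favours their rise, so that shift may rest in part on them.

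Of 5 TAS and IPS RNAs, 3 rose with RNase R in Col-0, 1 fell and 1 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.00185, and adjusted p = 0.157 with an estimated correlation). TAS3, a precursor of trans-acting small RNAs, rose from 4.61 ± 0.44 to 41.7 ± 4.7 FPKM and TAS2 from 2.49 ± 0.13 to 5.35 ± 0.67, and both turned in direction as TPM (log2 fold change −0.17 and −1.75). Of 23 splicing factors, 5 rose, 11 fell and 7 did not pass (5 and 11 adjusted over the list alone), with a camera shift above other loci (adjusted p = 0.0243, and adjusted p = 0.588 with an estimated correlation) that turned in direction as TPM (adjusted p = 0.947). U2AF65A (log2 fold change −1.82) and RS31 (−1.23) fell, whereas RS40 (1.32) and GRP7 (1.53) rose, the latter pair turning to −1.82 each as TPM. Of 36 miRNA targets, 8 rose, 17 fell and 11 did not pass (8 and 17 adjusted over the list alone), with a camera shift above other loci (adjusted p = 0.00659, and adjusted p = 0.506 with an estimated correlation) that also turned as TPM (adjusted p = 0.947), and SPL4 (−1.65) and CSD1 (−2.91) fell.

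The other lists had no camera call in Col-0. Of 16 green tissue genes 13 fell with RNase R (13 adjusted over the list alone; camera adjusted p = 0.164), with the plastocyanin gene PETE2 at a log2 fold change of −3.86 and the Rubisco subunit gene RBCS1B, 1 of a family of similar copies, from 62.3 ± 10 to 2.76 ± 0.41. Of 14 housekeeping genes 11 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 0.454), with ACT7 from 76.5 ± 1.5 to 20.7 ± 0.22 FPKM and UBQ10 from 104 ± 5.7 to 31.5 ± 2.0. Of 16 floral identity and meristem genes 13 fell and 2 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.889), among them STK (−1.83), PI (−2.10) and AP3 (−2.18). Of 12 tapetum and pollen wall genes 10 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.38), with the oleosin gene GRP19 at −2.43. Falls also led in RNA decay and surveillance (14 of 15; 14 adjusted over the list alone; camera 0.157) and the small RNA machinery (16 of 22, 1 rose; 16 and 1 adjusted over the list alone; camera 0.921). They led also in abiotic and heat stress (6 of 10, 1 rose; 6 and 1 adjusted over the list alone; camera 0.921), mature pollen (3 of 4; 3 adjusted over the list alone; camera 0.921) and the immune response (3 of 4, 1 rose; 3 and 1 adjusted over the list alone; camera 0.889).

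In all, 11375 loci passed for RNase R in Col-0, 1187 higher and 10188 lower, with a median log2 fold change of −0.66, relative to which RPL23AA stood at −4.11 and BXL3 at 6.43. The split depended on the scaling: 3909 higher to 4571 lower with median ratios (median −0.07), 4192 to 4260 with quantile normalization, 197 to 13957 as TPM (median −2.67) and 203 to 13839 after removal of organelle and ribosomal RNA loci (median −3.14). The minimum log2 fold change of 1 left 4643 calls and the mean FPKM of at least 5 left 2713. Under all 5 scalings 189 loci were higher, 132 of them opposite-strand loci, and 3866 were lower, while 4125 were called in opposite directions.

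RNase R against none in dbr1-2 asks the same of the mutant, and a rise in FPKM again does not by itself show resistance. AT5G64160 rose from 7.80 ± 0.065 FPKM without RNase R to 254 ± 11 with it (SD, n = 2 each; log2 fold change 4.86, SE 0.11, limma adjusted p = 2.62e-07), and TOE2 rose from 2.84 ± 0.11 to 44.0 ± 0.84 FPKM (3.55, SE 0.09), a call lost after removal of organelle and ribosomal RNA loci (0.43, adjusted p = 0.127). AT2G31141 rose from 1102 ± 6.5 to 47172 ± 10000 FPKM, RR3 from 737 ± 95 to 22899 ± 1900 and AT1G49700 from 2.77 ± 0.069 to 119 ± 13. AT3G44010 (chromosome 3 from 15799481 to 15801227), of the S29 ribosomal protein family, fell from 72.3 ± 7.7 to 3.33 ± 0.66 FPKM, and AT2G25210 from 42.9 ± 9.3 to 1.45 ± 0.56. PETE2 fell from 121 ± 11 to 12.6 ± 1.2 FPKM and RBCS1B from 109 ± 7.2 to 5.94 ± 0.85.

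The largest listed rises among protein-coding genes were AT4G23420 (log2 fold change 5.48, SE 0.44), AT2G31141 (5.40, SE 0.18), AT5G26990 (5.34, SE 0.45), AT1G49700 (4.99, SE 0.10), RR3 (4.96, SE 0.19) and AT5G64160. The largest falls were AT2G35750 (−6.52, SE 0.24), AT2G07687 (−4.55, SE 0.13), which shares its listed interval with other loci, AT2G05760 (−4.49, SE 0.18), AT2G25210 (−4.17, SE 0.19) and AT3G44010 (−4.09, SE 0.14). Opposite-strand loci led the other loci: the one at AT4G14713 was at 0 and 2.89 FPKM without RNase R and at 564 and 436 with it, and the one at AT1G78300 at 8.99 and 7.8 and at 966 and 330. The opposite-strand locus at AT3G51140 rose from 5.95 ± 1.8 to 302 ± 5.8 FPKM and that at AT1G72480 from 0.70 ± 0.59 to 72.7 ± 25, followed by rps14 (log2 fold change 5.38, SE 0.20). Of 310 opposite-strand loci, 299 rose with RNase R in dbr1-2 and 8 fell, with a median of 2.91, a split that the expression filter sets in part.

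Of 13256 protein-coding loci, 1622 rose with RNase R in dbr1-2 and 9551 fell, of which 23 and 4025 did so under all 5 scalings (camera adjusted p = 1.07e-25 for a shift below other loci, and adjusted p = 0.0866 with an estimated correlation). Here too the few loci set against them include opposite-strand loci, whose rise the filter favours. Chloroplast loci were higher relative to other loci (38 higher, 20 lower of 68; camera adjusted p = 7.24e-13, kept with adjusted p = 0.0395 with an estimated correlation). The same was called for snRNA (5 higher of 5; camera 0.000123, and adjusted p = 0.322 with an estimated correlation) and pseudogenes and transposable elements (30 higher, 34 lower of 86; camera 2.24e-05, and adjusted p = 0.184 with an estimated correlation). It was also called for MIR primary transcripts (5 higher, 3 lower of 13; camera 0.00313, and adjusted p = 0.184 with an estimated correlation) and other non-coding RNA (35 higher, 68 lower of 128; camera 0.0121, and adjusted p = 0.488 with an estimated correlation). Genes lying inside an intron of another gene on its strand were also higher relative to other loci (3 higher, 1 lower of 5; camera 0.00812, and adjusted p = 0.184 with an estimated correlation). Of 23 splicing factors 7 rose, 6 fell and 10 did not pass (7 and 5 adjusted over the list alone), with a camera shift above other loci (adjusted p = 0.00642, and adjusted p = 0.528 with an estimated correlation). RS40 (log2 fold change 2.56) and the SR-like gene SCL30A (2.09) rose, and both turned in direction as TPM (−0.66 and −1.02). DDL, a forkhead-domain protein of miRNA processing, rose (2.28) and turned to −0.46 as TPM, and TAS3 rose (2.30) and turned to −0.94.

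The other lists had no camera call in dbr1-2. Of 36 miRNA targets 6 rose and 19 fell with RNase R (6 and 18 adjusted over the list alone; camera adjusted p = 0.204), TOE2 being the member with the smallest p. Of 16 green tissue genes 15 fell and 1 rose (15 and 1 adjusted over the list alone; camera 0.0858). Of 14 housekeeping genes 12 fell and 1 rose (12 and 1; camera 0.222), with ACT7 at −1.96. Of 16 floral identity and meristem genes 12 fell and 1 rose (12 and 1; camera 0.439), with STK at −1.83. Of 12 tapetum and pollen wall genes 10 fell and 1 rose (10 and 1 adjusted over the list alone; camera 0.313), with GRP19 at −2.48. Counts of falls and rises were 14 and 1 of 22 in the small RNA machinery (camera 0.912). They were 11 and 1 of 15 in RNA decay and surveillance (camera 0.553), 8 and 1 of 10 in abiotic and heat stress (camera 0.554). They were 3 and 1 of 4 in the immune response (camera 0.726), 1 and 1 of 4 in mature pollen (camera 0.439) and 2 and 3 of 5 in TAS and IPS RNAs (camera 0.0635), and adjusted over the list alone each count was the same.

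In all, 12098 loci passed for RNase R in dbr1-2, 2159 higher and 9939 lower (median log2 fold change −0.69, relative to which AT5G64160 stood at 5.55 and AT3G44010 at −3.39). The split was 4280 to 4796 with median ratios (median −0.09), 3818 to 5178 with quantile normalization, 274 to 13856 as TPM (median −2.69) and 256 to 13740 after removal of organelle and ribosomal RNA loci (median −3.24). The same minimum fold left 5536 calls and the FPKM minimum 2882. Under all 5 scalings 252 loci were higher, 202 of them opposite-strand loci, and 4172 were lower, while 4100 were called in opposite directions. Calls in the 2 genotypes overlapped in 1005 higher (178.6 for independent lists) and 9054 lower loci (7055.9) from 1 fit with a common spread per locus, and in 991 higher (174.8) and 8888 lower (6936.6) from separate fits of 4 libraries each. Without dbr1-2 replicate 1 with RNase R, 12035 loci passed, 2028 higher and 10007 lower.

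The interaction asks whether RNase R acted differently on an RNA in dbr1-2 and in Col-0. ADF11 changed from 0.281 ± 0.020 to 1.13 ± 0.16 FPKM with RNase R in Col-0 and from 2.47 ± 0.26 to 82.5 ± 4.8 in dbr1-2 (SD, n = 2 each; difference of log2 fold changes 3.86, SE 0.15, limma adjusted p = 2.98e-05). Adding 1 to the FPKM shrinks the change at the low Col-0 values more, so 3.86 overstates the difference for ADF11. AT1G23440 changed from 3.18 ± 0.37 to 2.2 ± 0.033 FPKM in Col-0 and from 6.11 ± 0.28 to 51.4 ± 12 in dbr1-2 (3.24, SE 0.22). ARPC1B went from 1.02 ± 0.059 to 1.53 ± 0.54 FPKM in Col-0 and from 2.11 ± 0.28 to 34.1 ± 0.27 in dbr1-2 (3.19, SE 0.21), and TOE2 from 1.73 ± 0.071 to 3.13 ± 0.21 and from 2.84 ± 0.11 to 44.0 ± 0.84 (2.95, SE 0.12). U2AF65A went from 8.57 ± 0.48 to 1.71 ± 0.21 FPKM in Col-0 and from 7.70 ± 0.15 to 6.78 ± 1.3 in dbr1-2 (1.65, SE 0.18). AT3G06435 went the other way, from 2.79 ± 0.022 to 48.3 ± 0.30 FPKM in Col-0 and from 0.845 ± 0.038 to 6.58 ± 0.13 in dbr1-2 (−1.66, SE 0.12).

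**Figure D3:**
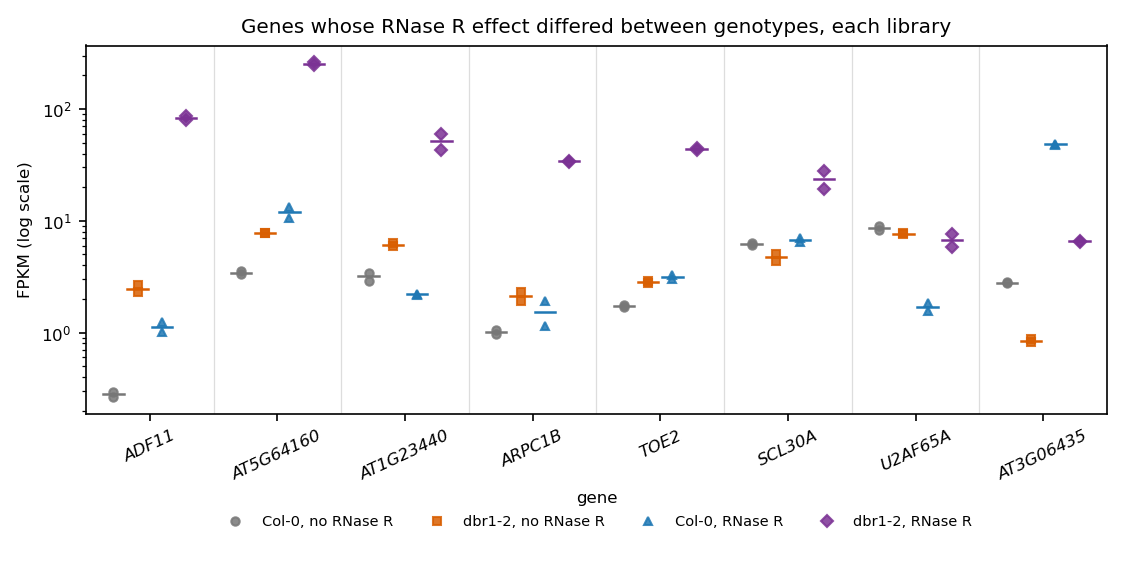
FPKM on a log scale of 8 genes in each of the 8 libraries, with a bar at the mean of each group of 2. ADF11, AT5G64160, AT1G23440, ARPC1B and TOE2 are highest in dbr1-2 with RNase R, U2AF65A is lowest in Col-0 with RNase R, and AT3G06435 is highest in Col-0 with RNase R.

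Other positive differences were those of AT4G03360 (5.17, SE 0.79), AT4G04200 (3.37, SE 0.37) and AT5G64160 (3.33, SE 0.16), the call of AT4G03360 being lost with quantile normalization and its value being 6.20 and 4.13 without Col-0 replicate 1 and 2 without RNase R. AT3G63052 (−1.71, SE 0.29) and PSBX, a subunit of photosystem II (−1.27, SE 0.22), had the other large negative ones, and both calls were lost after removal of organelle and ribosomal RNA loci and with the year as covariate. Among other loci, psbA was listed at 0 in 6 libraries, the unnamed locus XLOC_008009 differed by 4.22 (SE 0.61), AT1G25098 by 4.14 (SE 0.38) and the opposite-strand locus at AT3G06435 by −2.17 (SE 0.19), a call lost with pseudocounts of 0.1 and 0.01.

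Of 23 splicing factors, 6 had a positive and 1 a negative difference and 16 did not pass (7 and 1 adjusted over the list alone; camera adjusted p = 0.322), among them RS31 (1.17) and SCL30A (1.98). Of 36 miRNA targets, 5 were positive, 3 negative and 28 did not pass (5 and 3 adjusted over the list alone; camera adjusted p = 0.589), with SPL15 at 1.79 and PHV at −0.81. RRP6L1 (1.40) was the member that passed among 15 genes of RNA decay and surveillance (1 adjusted over the list alone; camera adjusted p = 0.589). Of 14 housekeeping genes 1 was positive, UBC21 (1.1), and 2 negative (1 and 2 adjusted over the list alone; camera 0.249). Of 10 abiotic and heat stress genes 1 was positive and 2 negative (1 and 3 adjusted over the list alone; camera 0.499), with RAB18 at −1.04. The calls of PHV and UBC21 were lost as TPM, after removal of organelle and ribosomal RNA loci and with the tag year as covariate (limma adjusted p = 0.0553 and 0.052), and that of RS31 after the removal. The call of RAB18, which fell with RNase R from 0.498 ± 0.014 to 0.153 ± 0.029 FPKM in Col-0 and from 7.84 ± 0.043 to 2.31 ± 0.037 in dbr1-2, was lost with median ratios (0.0553) and with pseudocounts of 0.1 and 0.01 (differences of −0.48 and −0.11, limma adjusted p = 0.25 and 0.839). Positive and negative counts were 2 and 1 of 16 green tissue genes (2 and 2 adjusted over the list alone; camera 0.499), 1 and 0 of 22 small RNA machinery genes (1 and 0; camera 0.596) and 1 and 0 of 16 floral identity and meristem genes (0 and 0; camera 0.499). By limma, 0 passed of 12 tapetum and pollen wall genes (1 at an unadjusted p under 0.05; camera 0.87, fry 0.706) and of 4 mature pollen genes (2 unadjusted, both positive adjusted over the list alone; camera 0.336, fry 0.121). The same count was 0 of 4 immune response genes (1 unadjusted; camera 0.499, fry 0.0322) and 0 of 5 TAS and IPS RNAs (2 unadjusted; camera 0.336, fry 0.25).

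Among annotation classes, protein-coding loci were shifted below other loci (1299 positive, 374 negative of 13256, and 286 and 41 under all 5 scalings; camera adjusted p = 0.00885, and adjusted p = 0.829 with an estimated correlation) with a median of 0.00 and a mean of 0.08. Mitochondrial loci were shifted below other loci too (2 positive, 9 negative of 68; camera adjusted p = 0.00885, and adjusted p = 0.829 with an estimated correlation). Genes with no intron held 69 positive and 74 negative calls of 1495 (camera 0.0538), genes with 1 to 4 introns 536 and 153 of 5459 (camera 0.794), and genes with 5 or more introns 735 and 158 of 6550 (camera 0.755). Genes inside an intron of another gene held 3 positive calls of 5 on the same strand (camera 0.0824) and 2 positive and 2 negative of 10 on the other (camera 0.851). Of 3 tested tRNA loci 1 was negative (camera 0.63), and the single ribosomal RNA locus, too few for a set test, did not pass. Opposite-strand loci held 125 positive and 6 negative calls of 310 (43 and 3 under all 5 scalings), with a median of 0.77. They are among the few loci that camera set against protein-coding ones, and the filter favours their rise. The shift of protein-coding loci may rest on this and need not be a trait of these loci.

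In all, 1973 loci passed in the interaction, 1544 positive and 429 negative (median 0.01). The split was 1265 to 1127 with quantile normalization, 989 to 661 as TPM and 523 to 352 after removal of organelle and ribosomal RNA loci, and 359 positive and 55 negative loci were called under all 5 scalings, with 8 called in opposite directions. Of the 1973 calls, 1591 were kept in direction with quantile normalization, 881 as TPM and 517 after that removal, so those splits hold other loci too. The calls fell to 878 without Col-0 replicate 1, 947 without Col-0 replicate 2, 991 without dbr1-2 replicate 1 and 863 without dbr1-2 replicate 2, all of them libraries without RNase R. A mean FPKM of at least 5 left 743 and the minimum fold 877. With the year of the tag as covariate 676 were left (609 positive, 67 negative). Genotype and year cannot be told apart among the libraries with RNase R. Without dbr1-2 replicate 1 with RNase R 2460 passed, 1577 positive and 883 negative.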

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

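The tests of a difference in digestion and of intron content, and the bins of the latter, were chosen only after the result was seen. The interaction of genotype and RNase R, tested in limma, passed at 1973 loci, 1544 of them with a larger rise or smaller fall in dbr1-2.

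For that pattern, library year as seen without RNase R would need those loci to differ between the years of the tags, but their median difference, later against earlier year, was −0.02 on the log2 scale (quartiles −0.08 to 0.03), against a median interaction of 1.03, which argues against it. A difference between the digestions or libraries of the 2 genotypes cannot be told apart from genotype, because each genotype's RNase R libraries carry tags of 1 year. With the year as covariate 676 calls were left, 604 of the rises among them, while over all 1544 rises the median fold went from 1.03 to 1.00 and its median SE from 0.17 to 0.21. RNA kept from introns in dbr1-2 stays open as a hypothesis: genes with an intron had interaction rises more often than genes with no intron in all 4 bins of mean FPKM without RNase R (odds ratios 2.30, 4.82, 2.52 and 1.81 from the lowest bin up; Fisher's exact test, adjusted p = 6.94e-06, 2.25e-07, 0.00062 and 0.0171), a difference between genes that does not set genotype apart from digestion. The lowest of these bins ran from 0 to 1.65 FPKM, so loci in it could pass the expression filter by rising with RNase R. In bins over all 8 libraries, where a rise itself moves a locus up, the odds ratio went from 1.05 in the lowest bin (Fisher's exact test, adjusted p = 0.917) to 4.35 in the highest. Whether each bin shows the difference thus depends on the binning. Fisher's test takes genes as independent replicates, which they are not. For genes with no intron, camera gave an adjusted p of 0.0538 in the interaction, and of 0.829 with an estimated correlation.

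The named loci past the threshold in the interaction follow as values. Among protein-coding genes the interaction was 5.17 for AT4G03360, 3.86 for ADF11, 3.37 for AT4G04200, 3.33 for AT5G64160, 3.24 for AT1G23440 and 3.19 for ARPC1B. It was −1.71 for AT3G63052, −1.66 for AT3G06435 and −1.27 for PSBX. Among other loci it was 4.22 for XLOC_008009, 4.14 for AT1G25098 and −2.17 for the opposite-strand locus at AT3G06435. List members had 2.95 (TOE2), 1.98 (SCL30A), 1.79 (SPL15), 1.65 (U2AF65A), 1.40 (RRP6L1), 1.17 (RS31), 1.1 (UBC21), −0.81 (PHV) and −1.04 (RAB18). The RAB18 value was −0.48 and −0.11 with pseudocounts of 0.1 and 0.01 (limma adjusted p = 0.25 and 0.839), and its FPKM fell with RNase R from 0.498 to 0.153 in Col-0 and from 7.84 to 2.31 in dbr1-2. Protein-coding and mitochondrial loci each had a camera adjusted p of 0.00885 for a shift below other loci, which became 0.829 with an estimated correlation in both. The loci set against protein-coding ones are few and include opposite-strand loci, whose rise the filter favours.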

How the results depend on the processing

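Removal of doubtful zeros was the alternative chosen only after the data were seen, and it left the count of loci in each of the 5 comparisons within 1.5 times. Where a value below changed, the cause was not tested, except that a mean FPKM of at least 5 and a minimum fold leave less to call by construction. The main fit shares 1 spread per locus over groups of unlike scatter (array weights 2.01 to 2.44 without RNase R and 0.403 to 0.507 with it). That spread is too large for libraries without RNase R and too small for those with it. The order of 2518 and 5315 calls between genotypes turned with only the 4 libraries compared (5847 and 2633), so it does not rank the genotype effects. Between genotypes without RNase R, 2518 calls became 1467 and 1276 with pseudocounts of 0.1 and 0.01, 934 at a mean FPKM of at least 5, 1197 with median ratios, 6307 with array weights, 5847 with only the 4 libraries compared, 356 with the minimum fold and 819 to 864 without 1 library. With RNase R, 5315 became 1771 at the mean FPKM filter, 1715 as TPM, 1230 without organelle and ribosomal RNA loci, 3453 with array weights, 2633 with only 4 libraries, 2423 with the tag year and 1368 with the minimum fold, and 4791 to 5737 without 1 library. RNase R in Col-0 gave 2713 at the mean FPKM filter and 4643 with the minimum fold, and in dbr1-2 2882 and 5536. The interaction gave 743 at the mean FPKM filter, 875 without organelle and ribosomal RNA loci, 676 with the tag year, 877 with the minimum fold and 863 to 2711 without 1 library, with 863, 878, 947 and 991 for the 4 libraries without RNase R. The replicate block gave 1781, 5986, 11301, 12134 and 1910 in the 5 comparisons. A count of like size can still hide lost calls. As TPM, 881 of 1973 interaction calls were kept in direction. Quantile normalization kept 3589 of 5315 calls between genotypes with RNase R. Median ratios kept 5758 of 11375 calls for RNase R in Col-0 and 6955 of 12098 in dbr1-2.

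Of 25 set calls, 2 held with an estimated correlation (23 were lost), 15 with median ratios (10 lost, 16 calls in all), 15 with quantile normalization and 18 as TPM, and fry, which tests against 0 and not against other loci, made 81 calls, 11 of the 25 in the same direction. Its direction differed for genes with no intron between genotypes with RNase R (adjusted p = 0.0228), for splicing factors (0.0391), miRNA targets (0.0111), MIR (0.152), other non-coding RNA (0.00164), pseudogenes and transposable elements (0.0315) and mitochondrial loci (0.00103) in Col-0, for other non-coding RNA in dbr1-2 (0.0123) and for protein-coding loci in the interaction (0.298). In Col-0, chloroplast loci turned with quantile normalization (0.973) and splicing factors and miRNA targets as TPM (0.947 each). As TPM and without organelle and ribosomal RNA loci, log2 fold changes with RNase R turned to −0.17 and −0.09 (TAS3), −1.75 and −1.88 (TAS2), −1.82 and −1.79 (RS40) and −1.82 and −1.73 (GRP7) in Col-0, and to −0.66 and −0.73 (RS40), −1.02 and −1.12 (SCL30A), −0.94 and −1.02 (TAS3) and −0.46 and −0.55 (DDL) in dbr1-2. Of named genes, 20 of 32, 28 of 35, 25 of 29, 21 of 26 and 13 of 21 in the 5 comparisons kept direction and call under each alternative in which they were tested, the minimum fold not counted, and 19, 26, 25, 21 and 13 of them also reached that fold. The depth with RNase R, 8.6 to 12.7 reads per FPKM on 1 kb of reduced length, limits values near the filter.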

Other observations

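The test of background reads, the test of green tissue and the clock lists themselves were chosen only after results had been seen. Opposite-strand loci stood far above their own-strand partners after RNase R. Over 263 genes, the median ratio of the opposite-strand to the own-strand FPKM was 0.109 and 0.112 in the Col-0 libraries without RNase R, 0.175 and 0.153 in those of dbr1-2, 3.58 and 3.78 in Col-0 with RNase R and 8.09 and 7.85 in dbr1-2 with it. The strand of these loci is inferred from locus numbering, and libraries with RNase R alone could bring a locus past the expression filter.

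For these loci, reads of the gene's own exons on the wrong strand would move both strands alike. With RNase R in dbr1-2 the log2 fold change of the opposite strand exceeded that of the own strand by a median of 3.93 (quartiles 2.81 to 4.70, higher in 256 of 263 genes). For the loci tested, this argues against such reads. The expression filter, which 310 of 364 opposite-strand loci passed, could admit a locus by its rise. The size of the difference and the count of genes therefore follow in part from the filter. Wrong-strand reads of introns or unspliced RNA need not move with the own-strand value, so the comparison cannot decide on them. Whether counting used the strand is not given. DNA reads on both strands alike would need an own-strand FPKM in dbr1-2 with RNase R no lower than the opposite-strand increase over Col-0. The median ratio of the former to the latter was 0.196 (quartiles 0.0617 to 0.617, below 1 in 203 of 236 genes with an increase). For these genes, that argues against such reads as the whole source of the larger rise, as far as the inferred strands hold. The ratio was taken only over genes with an increase, which the filter could favour, and library year is confounded with genotype there. Resistant RNA tied to introns may contribute, but an intron is common (279 of 284 such genes, and 11896 of all 13256 tested protein-coding genes), and across these loci, which are not independent replicates, Spearman's rho of the interaction with the longest intron was −0.02 (permutation p = 0.728), so this stays open.

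Clock genes changed between genotypes without RNase R, in lists written after the clock-controlled gene GRP7 had been seen. Of 7 tested morning genes 6 rose and 1 fell (median 1.04; camera p = 0.000211, p = 0.0188 with an estimated correlation), with CCA1 at 1.82, RVE1 at 1.77 and PRR7 at −0.74. Of 9 evening genes 4 fell (median −0.38; camera p = 1.7e-08, p = 0.00563 with an estimated correlation), with FKF1 at −1.38, PRR5 at −1.24, GI at −0.86 and PCL1 at −0.70.

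Harvest at another time of day is a candidate explanation, since the morning median lay 1.42 above the evening one, the direction it needs. More green tissue in dbr1-2 stays open too: in the green tissue list 6 of 16 members rose and 3 fell (median 0.44; fry adjusted p = 0.0184 for a rise). Camera made no call for the list against other loci (adjusted p = 0.434, and adjusted p = 0.773 with an estimated correlation), and fry also pointed up for housekeeping genes (0.0129) and protein-coding loci (0.0292). The 3 falls, named after their values had been seen, were those of LHCB1.1, LHCB1.2 and LHCB1.3, neighbouring similar copies that may share reads and so count as 1 family. Adjusted over the list alone, 7 members rose and 4 fell, which adds a fall beyond these 3. An effect of dbr1-2 on the clock itself stays open and was not tested, and the hour of harvest is not given in the sources used here.

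The non-coding locus AT1G15405 was listed at 0 in Col-0 replicate 1 with RNase R and at 934126 FPKM in replicate 2. It made up 24.77% of the FPKM total in the latter, and was listed at 396224 and 417623 in the dbr1-2 libraries with RNase R. It enters the totals used for TPM and after removal of organelle and ribosomal RNA loci, as does the snRNA locus U1.5. In Col-0 without RNase R, U1.5 held 19.9% and 10.51% of the total. Whether organelle RNA or such single loci ended calls under those scalings was not tested.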
